A study of Mus musculus with 6 samples.

How the data were processed

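Hippocampal RNA of 3-month-old female C57BL/6 mice was measured on 6 Affymetrix Mouse Genome 430 2.0 arrays, 3 of p300+/- and 3 of wild-type pools, each pool made of equal amounts of RNA from 4 animals. Per the labels' protocols, RNA was extracted with Trizol and cleaned on RNeasy columns, and the array data were processed and normalized in GeneSpring GX. The software version, the summarization of probes into probe sets, the normalization between arrays and any filter are not given in the sources used here. The deposited table held 1 value per probe set and array for 45101 probe sets. The median of each tested probe set's 6 values was 0 within 1e-06, so the deposited log2 values are differences from the probe set's own median and hold no absolute level. Column medians ran from -0.014 to 0.023 (p300+/- 0.0061, -0.0052 and 0.0073, wild-type -0.014, 0.023 and -0.0064, replicates 1 to 3).

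The base of the logarithm is not stated. It was taken as 2 from the values themselves, because 97.5% of the tested probe sets had values on binary grids of differences between single-precision numbers. Numbers of 2 to 16, the span of log2 array intensities, leave such grids. Grids outside that span were counted with the nearest class, and the grids alone do not exclude another base. The direction of a difference does not depend on this, but a fold change does. The same grids gave each probe set a coarse level class. The class from 8 to 16 held 12287 probe sets (27.3%), that from 4 to 8 held 23708, that from 2 to 4 held 7907, and 1135 were not assigned. On levels simulated in the assumed format this assignment was right for 99.4% of 18638 probe sets. Simulated probe sets whose values crossed a class boundary were not counted.

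Genes were named through the platform annotation, with symbols updated by gene identifier to the RefSeq table of assembly GRCm38.p6. After 64 control probe sets were left out, 34945 probe sets had a single gene symbol, 932 had several and 9160 had none, and 34741 of the first kind matched the RefSeq table. The deposited values name no genome build, so this table was used only for names and for which genes neighbour each other, and no coordinates are printed.

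Each probe set was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), as p300+/- minus wild-type over all 6 arrays and without covariates. The test was two-sided with Benjamini-Hochberg adjustment over 45037 probe sets and a threshold of 0.05. The planned filter on dim probe sets was not applied, as the design provided for centred values. A planned stricter filter on the mean and a planned floor at a low percentile need levels and could not be run, and filters on the level class were used in their place. The test was tried on simulated data and on the real arrays with known changes added to 200 probe sets. With independent noise, 0 of 200 changes of 1.5-fold, 80 of 2-fold, 179 of 4-fold and 197 of 8-fold were called. On the real arrays 0, 0, 189 and 193 were called. Figures were drawn with matplotlib 3.10.9.

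A set of 26 gene lists, fixed with the design before the data were examined, covered regulators of acetylation, p300 partners, activity-regulated genes, synaptic and metabolic genes, stress responses, hippocampal cell types, and tissue or blood that a dissection could carry along. Of their 762 entries 675 were measured. Each gene was read by its first probe set in file order, giving 18194 genes. Lists were tested with camera (limma) at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists. Camera compares a list with all other genes. The alternatives were an estimated correlation and fry, which tests whether a list's genes move, on balance, in a single direction without reference to other genes. The values called relative to other genes are the list's mean log2 fold change minus that of all other genes. A few genes belong to more than 1 list, such as Igfbp2 (choroid plexus and vascular lists) and Dcn (vascular and CA1 lists).

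Genes were named by a rule set before the data were examined. It took every probe set of Ep300 and Crebbp, and 10 genes per direction past the threshold whose 3 arrays of a genotype lay beyond all 3 of the other. As none passed, the places were filled by the smallest unadjusted p under the same condition. From each list it took the 2 members with the smallest p where none passed, and near Ep300 the genes that passed. Camk2a, Syt1, Rasgrp1, Kif5c, Ttr and the pituitary hormone genes were chosen after their values were seen. Array quality was followed with the 18 hybridization, 24 poly-A and 3 18S control probe sets, array weights and principal components.

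Other settings comprised quantile normalization, median centring of arrays, eBayes with trend and robust moderation, array weights, the replicate number as a block, omission of probe sets that can bind several transcripts, a threshold of 0.1, windows of 5 and 20 Mb around Ep300, the mean over all probe sets of a gene, and each array left out in turn. Chosen after the data were seen were the level classes as filters, the brightest probe set of each gene, and p300+/- 3 and wild-type 2 left out or set against the other 4 arrays as a block.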

Results

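Gene expression was profiled in the hippocampus of mice heterozygous for a deficiency of p300 (p300+/-) and of their wild-type littermates. p300, the product of Ep300, is a lysine acetyltransferase that modifies histones and acts as a coactivator for many transcription factors. The comparison asked which hippocampal transcripts differed between these genotypes, in a study of physical and cognitive traits of mice with reduced p300. All animals were females of 3 months on a C57BL/6 background. RNA from 4 animals was pooled for each array and 3 arrays were made per genotype, so that 12 animals of each genotype entered the 6 arrays. The 3 pools of a genotype were described by the submitters as independent biological replicates. Each value on the Affymetrix Mouse Genome 430 2.0 arrays was a log2 intensity relative to that probe set's median over the 6 arrays, so that differences between arrays were kept and absolute levels were not. After control probe sets were left out, 45037 probe sets were tested, of which 34945 carried a single gene symbol. The number of arrays limited the precision. The median standard error of a log2 fold change was 0.15, and the median 95% interval reached 0.35 to either side.

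Ep300 itself was lower in the p300+/- hippocampus. Its only probe set (1434765_at) averaged -0.33 ± 0.15 (SD, n = 3) in p300+/- and 0.33 ± 0.099 (SD, n = 3) in wild-type pools, a log2 fold change of -0.66 ± 0.13 (SE). This was 0.634 times the wild-type level, with a 95% interval of 0.516 to 0.778. All 3 p300+/- arrays lay below all 3 wild-type arrays, and the probe set had the third smallest unadjusted p of those tested. The difference did not pass over all probe sets (limma, adjusted p = 0.9999). Among the 18 measured lysine acetyltransferases it was the only member to pass when adjusted over the list alone (limma, adjusted p = 0.0186). An exact two-sided permutation test of 3 against 3 arrays cannot give a p below 0.1. Whether the probe set reads the altered part of the allele is not given in the sources used here, so its value is a limited check of the labels. Crebbp, which encodes CBP, the closest relative of p300, was read by 4 probe sets. Their log2 fold changes were -0.034 ± 0.14, -0.035 ± 0.11, -0.51 ± 0.37 and -0.13 ± 0.13 (SE), and none passed. The first of these (1434633_at) changed sign when p300+/- 3 or wild-type 3 was left out, at 0.056 and 0.022. The third (1436983_at) moved most, from -0.86 without wild-type 2 and -0.84 without p300+/- 1 to -0.27 without wild-type 1. With an array left out the value of 1459804_at ran from -0.18 to -0.028, and that of 1435224_at from -0.073 to -0.00099. Of the Crebbp probe sets, 1459804_at was in the level class from 2 to 4 and the others in that from 8 to 16.

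**Figure D1:**
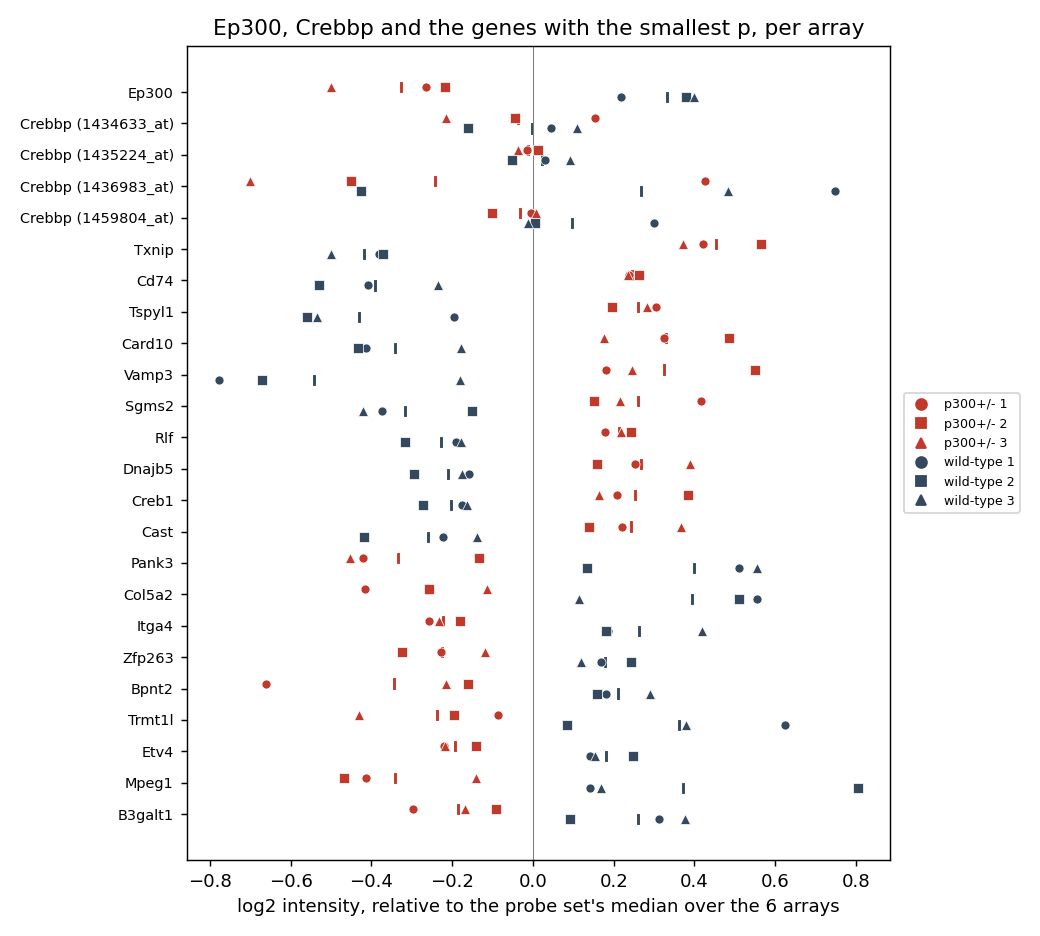
Log2 intensity of each array (x axis, relative to the probe set's median over the 6 arrays) for Ep300, the 4 probe sets of Crebbp and the other genes named by rule (y axis); symbols mark the 3 p300+/- and 3 wild-type arrays, and short vertical bars mark the mean of 3 arrays. The Ep300 values lie at -0.22 and below in p300+/- and at 0.22 and above in wild-type, whereas the genotypes overlap in each Crebbp probe set.

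Across the array no transcript passed the test between genotypes, and the genes below are values that did not pass. Txnip, which encodes an inhibitor of thioredoxin that also limits glucose uptake, had the smallest p. It was 1.83-fold higher in p300+/- pools, with a log2 fold change of 0.87 ± 0.11 (SE) and a 95% interval of 0.60 to 1.14. Its other probe set gave 0.37 ± 0.23. Cd74, the invariant chain that accompanies MHC class II molecules, was 1.56-fold higher at 0.64 ± 0.12. Vamp3, a SNARE protein of recycling endosomes, was at 0.87 ± 0.19, and its 4 other probe sets lay between 0.17 and 0.50. Creb1, the transcription factor that recruits CBP and p300 when phosphorylated, was at 0.46 ± 0.12, while its 5 other probe sets ran from -0.23 to 0.40. The remaining genes named on the higher side were Tspyl1 at 0.69, the NF-kappaB pathway scaffold Card10 at 0.67, the sphingomyelin synthase Sgms2 at 0.58, the calpain inhibitor Cast at 0.50, the co-chaperone Dnajb5 at 0.48 and the zinc finger gene Rlf at 0.44. The other probe sets of Rlf had the opposite sign (-0.20 and -0.18), and so had 1 probe set of Dnajb5 (-0.14), while another was at 0.10. The other probe sets of Tspyl1 (0.063), Sgms2 (0.27) and Cast (0.13 and 0.27) gave smaller values than the named probe sets.

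On the lower side, after Ep300, Pank3 had the smallest p. This pantothenate kinase, which starts coenzyme A synthesis, was at -0.73 ± 0.16 (SE), while its other probe set was at 0.087. Mpeg1, a pore-forming protein of macrophages and microglia, was at -0.71 ± 0.20, and the collagen chain Col5a2 was at -0.66 ± 0.16, with its other probe set at -0.097. Itga4, the integrin alpha 4 subunit, was at -0.49, and 3 of its 4 other probe sets were above 0. The others were Trmt1l at -0.60, the Golgi nucleotidase Bpnt2 at -0.56, the galactosyltransferase B3galt1 at -0.45, the zinc finger gene Zfp263 at -0.40 and the ETS factor Etv4 at -0.37. Other probe sets of these genes were nearer 0, at -0.057 and -0.0043 for Trmt1l, -0.12 and -0.011 for Bpnt2, -0.28 to 0.014 for B3galt1, -0.17 for Zfp263 and -0.055 for Etv4. In the named probe set of each gene the 3 p300+/- arrays lay on a single side of the 3 wild-type arrays, because the naming rule required it. The named probe sets of Ep300, Dnajb5 and Bpnt2 were in the level class from 8 to 16. That of Rlf was in the lowest class, from 2 to 4. All others named as higher or lower were in the class from 4 to 8.

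Over all probe sets, 0 were higher and 0 were lower past an adjusted p of 0.05, and the smallest adjusted p was 0.9999 (limma). At an unadjusted p under 0.05 there were 550 probe sets, 347 higher and 203 lower in p300+/-, or 1.22% of those tested. Evenly spread p-values would give 2252. Other splits of the 6 arrays, 3 against 3, gave from 266 to 7237, so 2252 is no firm baseline for these arrays. The genotypes did not overlap in 2426 probe sets (5.39%), where chance gives 10%. Changes of 2-fold added to 200 probe sets of these arrays were called in 0 cases and changes of 4-fold in 189. With simulated independent noise 80 of 200 changes of 2-fold were called. Each trial was a single draw of 200 probe sets, so it sets no general limit on what the test could call.

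Lists of transcriptional regulators did not pass the gene list test (camera, limma), which compares a list with all other genes. The 18 lysine acetyltransferases split into 9 with higher and 9 with lower values, with a mean log2 fold change of -0.018, a median of 0.019 and a downward direction in the test (adjusted p = 0.611, camera, limma). After Ep300 the smallest p in the list belonged to Taf1, at 0.24 ± 0.20 (SE). Of the histone deacetylases, 14 of 18 had higher values (mean 0.037, adjusted p = 0.847, camera, limma), with Hdac2 at -0.25 ± 0.19 and Sirt2 at 0.16 ± 0.15. Among 35 transcription factors known to bind p300, 19 were higher and 16 lower (mean 0.036, adjusted p = 0.911, camera, limma). The members with the smallest p were Creb1, whose probe set used for the lists gave 0.40 ± 0.17, and Myb at 0.34 ± 0.15. Histone genes split 7 to 7 (mean 0.039, adjusted p = 0.911, camera, limma), with H1f2, a linker histone, at 0.40 ± 0.14 and H2ax at 0.18 ± 0.14.

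Genes induced by neuronal activity, many of them targets of CREB, leaned upwards without passing. Values were higher for 32 of 41 members, with a mean log2 fold change of 0.074 ± 0.063 (SE over arrays; adjusted p = 0.170, camera, limma). The phosphatase gene Dusp1 was at 0.24 ± 0.11 and Klf2 at 0.23 ± 0.16. The list passed with wild-type 1 left out, at 0.098 relative to other genes (adjusted p = 0.0101, camera, limma), and was at 0.00021 with wild-type 3 left out. Glutamate receptors and postsynaptic density genes split 20 to 20 (mean 0.066 ± 0.15, adjusted p = 0.911, camera, limma). The kainate receptor subunit Grik1 was at -0.40 ± 0.12 and Cacng8, an AMPA receptor auxiliary subunit, at 0.54 ± 0.17. Of the genes for synaptic vesicles and release, 24 of 40 were higher (mean 0.068 ± 0.18, adjusted p = 0.911, camera, limma), with Vamp1 at 0.66 ± 0.32 and Vamp2 at 0.61 ± 0.34. Vamp1 and Vamp2 were lowest in wild-type 2, at -1.23 and -1.33. Both synaptic lists turned with single arrays. Leaving out wild-type 2 put them at -0.097 and -0.13 relative to other genes (adjusted p = 0.0125 and 0.00438, camera, limma), and leaving out p300+/- 3 put them at 0.14 and 0.15 (adjusted p = 0.0213 and 0.0115, camera, limma). The postsynaptic list also passed upwards without wild-type 1 (0.13) and the vesicle list without wild-type 3 (0.14).

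The neuronal cell type lists did not pass. Dentate granule cell markers were higher in 11 of 17 genes, with a mean of 0.034 and a downward direction in the test (adjusted p = 0.911, camera, limma). Trpc6 was at -0.25 ± 0.13 (SE) and Glis3 at -0.28 ± 0.15. With the brightest probe set of each gene the dentate list lay at -0.11 relative to other genes and passed (adjusted p = 0.00841, camera, limma). CA1 pyramidal markers had a mean of 0.043 and a median of -0.023 over 13 genes (adjusted p = 0.911, camera, limma), with the potassium channel gene Kcnh7 at 0.44 ± 0.16 and Dcn, a matrix proteoglycan, at 0.37 ± 0.15. For CA3 and CA2 markers 10 of 15 values were higher (mean 0.043, adjusted p = 0.911, camera, limma), among them Nnat at 0.30 ± 0.21, with Cadps2 at -0.15 ± 0.13. Markers of granule cell precursors and immature neurons had a mean of 0.0054 and a median of -0.0031 over 25 genes, with a downward direction in the test (adjusted p = 0.830, camera, limma). Calretinin (Calb2) was at 0.24 ± 0.12 and the proneural factor Neurog2 at -0.28 ± 0.17. GABAergic interneuron markers were higher in 17 of 23 genes (mean 0.092, adjusted p = 0.170, camera, limma). In that list the cannabinoid receptor gene Cnr1 was at 0.54 ± 0.18, followed by Calb2, and the list passed with p300+/- 1 left out, at 0.13 relative to other genes (adjusted p = 0.0112, camera, limma).

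**Figure D2:**
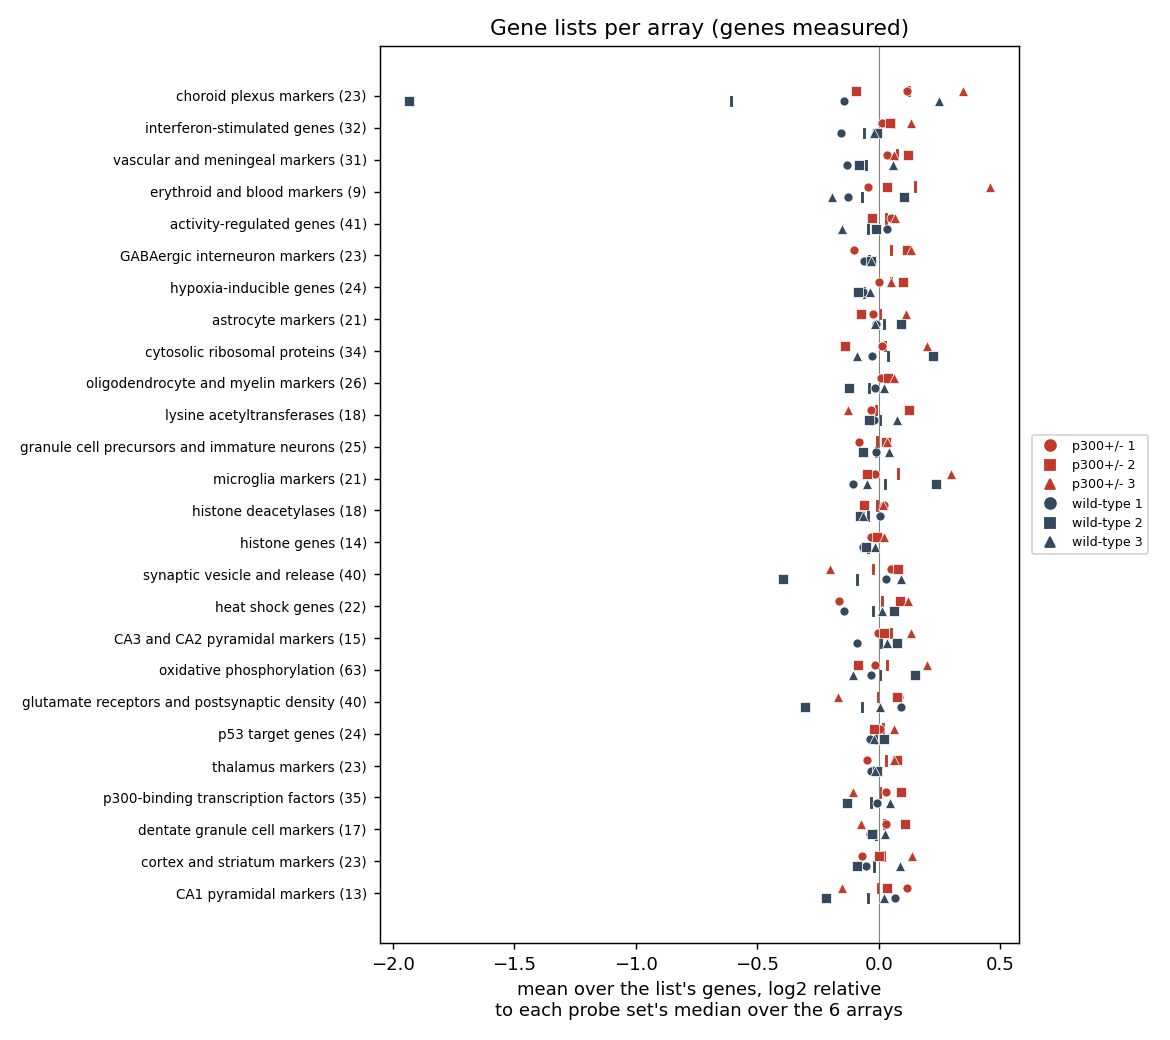
Mean over the measured genes of each fixed gene list (y axis, number of genes in brackets) in each array, as log2 relative to each probe set's median over the 6 arrays (x axis); symbols mark the arrays and short vertical bars the mean of 3 arrays. The choroid plexus list lies at -1.93 in wild-type 2 and between -0.14 and 0.35 in the other arrays.

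Choroid plexus markers were higher in p300+/- than in wild-type pools, and the difference lay in a single wild-type array. The choroid plexus is the secretory epithelium that borders the dissected tissue and makes cerebrospinal fluid. Of 23 measured markers 22 had higher values, with a mean log2 fold change of 0.73 ± 0.68 (SE over arrays). The list passed with the preset correlation of 0.01 between genes (adjusted p = 1.33e-07, camera, limma) but not with an estimated correlation (adjusted p = 0.752, camera, limma). The list mean was -1.93 in wild-type 2, against -0.14 and 0.25 in the other wild-type arrays and 0.12, -0.095 and 0.35 in p300+/-. Ttr, the transthyretin gene and the most abundant choroid plexus transcript, was read by 4 probe sets that lay at -3.20 to -2.06 in wild-type 2, relative to their medians over the 6 arrays. Without that array the mean log2 fold change was 0.069 ± 0.23, and the list no longer passed (adjusted p = 0.938, camera, limma). No member passed over all probe sets or when adjusted over the list alone. The members with the smallest p were Kl, the gene of the klotho protein, at 0.90 ± 0.52 and Lbp at 0.24 ± 0.14. The Kl probe set used was at -2.13 in wild-type 2, and another, in the level class from 8 to 16, gave 0.013 ± 0.12.

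Interferon-stimulated genes were slightly higher as a group in p300+/- pools. Values were higher for 26 of 32 members, with a mean log2 fold change of 0.12 ± 0.058 (SE over arrays). The list means of the 3 p300+/- arrays (0.013, 0.046 and 0.13) lay above those of the 3 wild-type arrays (-0.15, -0.0076 and -0.020). The list passed with the preset correlation (adjusted p = 0.00139, camera, limma) and not with an estimated correlation (adjusted p = 0.752, camera, limma). No member passed singly. Psmb8, a subunit of the immunoproteasome, was at 0.31 ± 0.11 (SE) and H2-K1, an MHC class I heavy chain, at 0.32 ± 0.13. Without wild-type 1 the list lay at 0.062 relative to other genes, in place of 0.098, and did not pass (adjusted p = 0.1304, camera, limma).

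Vascular and meningeal markers were higher by a similar amount. Of 31 genes 22 were higher, with a mean of 0.12 ± 0.062 (SE over arrays), and the list passed with the preset correlation (adjusted p = 0.00896, camera, limma) but not with an estimated correlation (adjusted p = 0.752, camera, limma). Dcn was again at 0.37 and Vtn, the vitronectin gene, at 0.28 ± 0.12. The list did not pass when p300+/- 2, wild-type 1 or wild-type 2 was left out (0.067, 0.069 and 0.064 relative to other genes), nor, at 0.088, without both p300+/- 3 and wild-type 2. Erythroid and blood markers were higher in 8 of 9 genes at a mean of 0.22 ± 0.18 and missed the threshold (adjusted p = 0.0548, camera, limma). Ngp, a granule protein of neutrophils, was at 0.43 ± 0.19 and the heme synthesis gene Alas2 at 0.46 ± 0.26. This list mean was 0.46 in p300+/- 3, and without that array the list lay at 0.059 relative to other genes, in place of 0.19. It passed without p300+/- 1, p300+/- 2 or wild-type 2 (0.28, 0.25 and 0.26).

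Glial lists did not pass. Microglia markers were higher in 13 of 21 genes (mean 0.050 ± 0.15, SE over arrays; adjusted p = 0.830, camera, limma), with Selplg at 0.20 ± 0.14 and the integrin gene Itgam at 0.23 ± 0.16. Astrocyte markers were lower in 12 of 21 genes (mean -0.016, adjusted p = 0.492, camera, limma), with the urea transporter Slc14a1 at -0.27 ± 0.13 and Hapln1 at 0.39 ± 0.22. Oligodendrocyte and myelin markers were higher in 17 of 26 genes (mean 0.076, adjusted p = 0.549, camera, limma), with Mal at 0.22 ± 0.11 and Mobp at 0.26 ± 0.14. Of the neighbouring brain regions, thalamus markers had higher values in 15 of 23 genes (mean 0.047, adjusted p = 0.911, camera, limma), with Prkcd at 0.32 ± 0.11 and Zic1 at 0.61 ± 0.22. Cortex and striatum markers were higher in 14 of 23 genes (mean 0.042, adjusted p = 0.911, camera, limma), with Rxrg at -0.22 ± 0.14 and Gpr6 at -0.20 ± 0.15.

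Stress and metabolic lists did not pass either. Hypoxia-inducible genes were higher in 16 of 24 cases, with a mean of 0.11 ± 0.032 (SE over arrays; adjusted p = 0.4004, camera, limma). Ddit4, an inhibitor of mTOR signalling, was at 0.54 ± 0.28 and the glucose transporter gene Slc2a3, read by 1 of its 4 probe sets, at 0.91 ± 0.49. Single wild-type arrays weighed on both. Ddit4 was at -1.07 in wild-type 1 (0.0027 and -0.057 in wild-type 2 and 3). Slc2a3 was at -1.54 in wild-type 2 (0.14 and -0.14 in wild-type 1 and 3). With the mean over all probe sets of a gene this list passed, at 0.082 relative to other genes (adjusted p = 0.0441, camera, limma). Genes activated by p53 split 12 to 12 (mean 0.028, downward in the test, adjusted p = 0.911, camera, limma), with Gtse1 at -0.20 ± 0.12 and Cdkn1a at 0.19 ± 0.12. Heat shock genes split 12 to 10 (mean 0.035, adjusted p = 0.911, camera, limma), with the small heat shock protein genes Hspb1 at 0.41 ± 0.23 and Cryab at 0.25 ± 0.16. The heat shock list passed when p300+/- 1 was left out, at 0.086 relative to other genes (adjusted p = 0.0451, camera, limma). Oxidative phosphorylation genes were higher in 45 of 63 cases, with a mean of 0.030 (adjusted p = 0.911, camera, limma), with Sdhc at 0.19 ± 0.13 and Uqcrc1 at 0.17 ± 0.13. Cytosolic ribosomal protein genes split 17 to 17 (mean -0.012, adjusted p = 0.509, camera, limma), with Rps9 at -0.15 ± 0.12 and Rpl37 at -0.20 ± 0.20. The ribosomal list passed downwards when p300+/- 3 or wild-type 3 was left out (-0.11 and -0.094 relative to other genes). It also turned upwards with another array left out, without passing. Over the 26 lists, 3 passed with the preset correlation, 0 with an estimated correlation and 0 with the rotation test fry, and no member of any list passed over all probe sets. Ep300 was the only member of any list to pass when adjusted over the list alone.

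The largest differences among the arrays did not follow genotype. The first principal component held 52.4% of the variance and set p300+/- 3 (43.3) and wild-type 2 (55.6) apart from the other 4 arrays (-30.7 to -12.6). The mean of the genotypes on it differed by 1.18. In those 2 arrays, against the other 4, the choroid plexus list had the largest shift, at -0.83, which came from wild-type 2 (-1.93, against 0.35 in p300+/- 3). Synaptic vesicle genes were at -0.36, glutamate receptor and postsynaptic genes at -0.30 and CA1 markers at -0.24, whereas erythroid and blood markers were at 0.36 (0.46 in p300+/- 3 and 0.10 in wild-type 2), microglia markers at 0.32, ribosomal protein genes at 0.27 and oxidative phosphorylation genes at 0.23. The other neuronal cell type lists were at 0.11 (CA3 and CA2), 0.068 (interneurons), -0.0086 (precursors and immature neurons) and -0.083 (dentate granule cells). Probe sets of some genes diverged in those 2 arrays. For Camk2a, the alpha subunit of the synaptic kinase CaMKII, a bright probe set (level class from 8 to 16) was at -2.46 and another at -0.24, and for the vesicle calcium sensor gene Syt1 the corresponding values were -2.43 and -0.26. Without these 2 arrays 0 probe sets passed and 1075 had an unadjusted p under 0.05 (limma), and Ep300 was at -0.55. No gene list passed, although the interferon and vascular values relative to other genes were 0.091 and 0.088, close to the 0.098 of each over all 6 arrays. With the 2 arrays kept as a block 4 lists passed at the preset correlation: choroid plexus, interferon, vascular and erythroid. An estimated correlation was not tried with the block. Array weights were lowest in wild-type 2 (0.38) and p300+/- 3 (0.58) and highest in wild-type 1 (3.17). Control probe sets also differed between arrays. The 18S mean was -1.32 in p300+/- 2 and -1.11 in wild-type 3, and -0.19 to 0.57 elsewhere. Poly-A controls ran from -0.45 in p300+/- 1 to 1.02 in wild-type 3. Hybridization controls ran from -0.89 in p300+/- 2 to 0.45 in p300+/- 3.

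**Figure D3:**
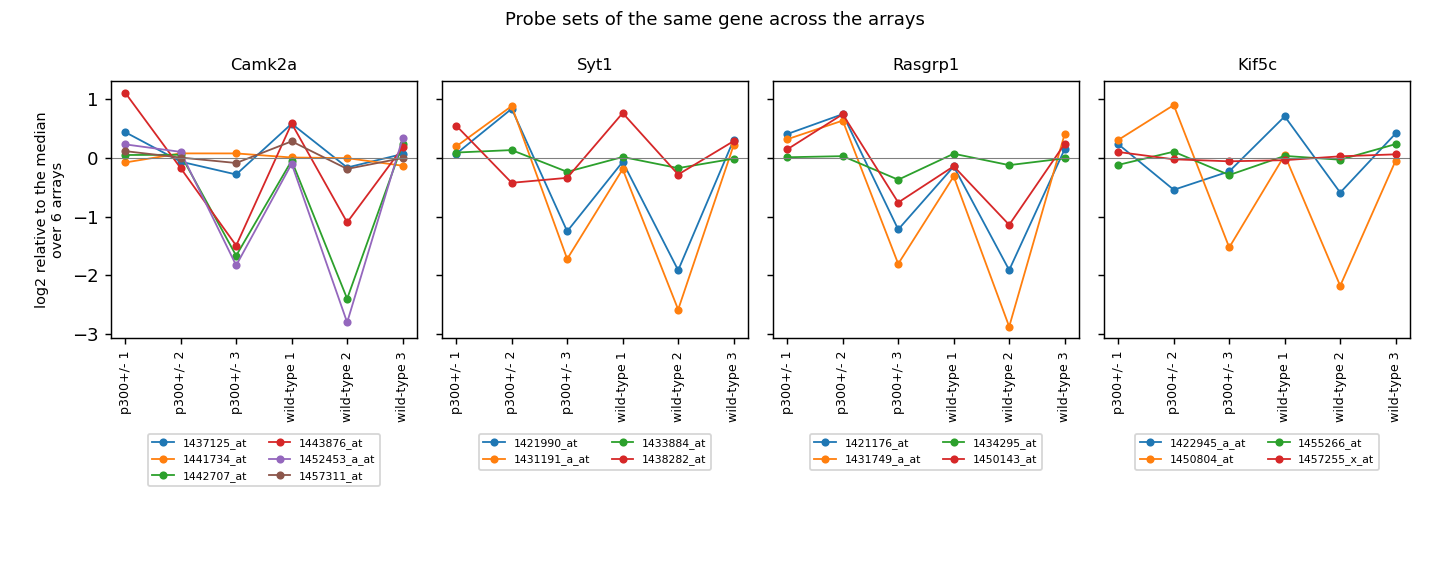
Log2 intensity relative to the median over the 6 arrays (y axis) of each probe set (lines) of Camk2a, Syt1, Rasgrp1 and Kif5c across the 6 arrays (x axis). In each gene at least 1 probe set lies well below the others in p300+/- 3 and wild-type 2; the bright Camk2a probe sets averaged between -2.46 and -0.24 in these arrays relative to the other 4.

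Genes near Ep300 were compared with all others because a targeted allele can carry neighbouring sequence from the strain of the cells in which it was made. Gene order was taken from assembly GRCm38.p6. Of 535 probe sets for 310 genes within 10 Mb of Ep300, 7 (1.31%) had an unadjusted p under 0.05, against 1.27% elsewhere. The odds ratio was 1.03 with a 95% interval of 0.408 to 2.15 (Fisher's exact test, two-sided, p = 0.846). Card10, at 0.67 ± 0.13 (SE) the neighbour with the smallest p, is among these 7, and whether its value comes from reduced p300 or from carried sequence was not tested. No neighbouring gene passed over all probe sets. With windows of 5 Mb and 20 Mb the odds ratios were 0.685 and 1.36, and neither differed from 1 (Fisher's exact test, p = 0.805 and 0.267).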

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

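The filters on level class, the brightest probe set of a gene and the treatment of the 2 arrays that stand apart were chosen after the data were seen. A stricter filter on the mean and a floor at a low percentile, both planned, were not run because centred values hold no level. Of 884 comparisons with the reported value, 754 kept direction and side of the threshold or, for counts, stayed of similar size. Many of them could not differ by construction, so this number does not measure stability. In every setting 0 probe sets passed the adjusted threshold (limma), and the log2 fold change of Ep300 stayed between -0.72 and -0.55. The naming rule required the genotypes not to overlap, so leaving out or weighting arrays could not turn the sign of a named gene. Several other settings leave the fold change as it was by construction. None of the 267 values of the 19 other named genes changed sign, which was thus largely fixed in advance. The lowest adjusted p among them was 0.0668, for Txnip with trend and robust moderation, where its adjusted p otherwise ran from 0.974 to 1.00 (limma). Signal over background cannot be had from centred values, so a limit set by dim probe sets could only be examined by class. The cause of the changes below was not tested unless stated.

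The count at an unadjusted p under 0.05 was 1632 with array weights, 93 in the class from 8 to 16 (fewer probe sets tested), 1075 without the 2 arrays that stand apart, 1706 with them as a block, and from 475 to 1151 with an array left out. The log2 odds ratio near Ep300 (0.038) was -0.76 with trend and robust moderation, -0.24 with array weights, 1.12 in the class from 8 to 16, 0.46 in the classes from 4 to 16, -0.55 within 5 Mb, -0.23 without the 2 arrays and -0.39 with them as a block, and from -0.65 to 0.74 with an array left out, with no Fisher's exact p under 0.05. The replicate number as a block gave 0 probe sets past the threshold and 604 at an unadjusted p under 0.05, and changed no other call. The labels do not say what a replicate number marks, so the numbers were not taken to pair the samples. Deviations of same-numbered arrays correlated at 0.609, -0.230 and -0.468 across probe sets. p300+/- 2, p300+/- 3, wild-type 2 and wild-type 3 did not correlate best with their own number. p300+/- 3 correlated best with wild-type 2 (0.648) and p300+/- 2 with wild-type 3 (0.369). Arrays may thus be matched across genotypes in another way, and no fit with such pairs was run.

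The following list values are log2 relative to other genes. Calls used the preset correlation of 0.01 unless an estimated correlation or fry is named. The choroid plexus list (0.71) did not pass with array weights (0.26), and was at -0.069 without the 2 arrays; with an estimated correlation and with fry its value of 0.71, like the interferon (0.098) and vascular (0.098) values, was the same by construction and did not pass. Without the 2 arrays the interferon (0.091) and vascular (0.088) lists did not pass. Erythroid markers (0.19) passed with quantile normalization (0.24), the mean over probe sets (0.18), the brightest probe set (0.20), the classes from 4 to 16 (0.19) and the 2 arrays as a block (0.19). Hypoxia genes (0.087) passed with the mean over probe sets (0.082). Lists that passed on neither side changed sign in 77 values. With quantile normalization these were deacetylases (-0.00093), p53 targets (-0.00058), oxidative phosphorylation (-5.7e-05) and cortex markers (-0.0090). With array weights they were deacetylases (-0.029), p300 partners (-0.0023), postsynaptic genes (-0.043), vesicle genes (-0.028), oxidative phosphorylation (-0.00095), CA1 (-0.033) and cortex markers (-0.012). With the mean over probe sets they were heat shock (-0.0018) and postsynaptic genes (-0.015) and dentate (-0.071), CA1 (-0.0069) and cortex markers (-0.0011). With the brightest probe set they were p300 partners (-0.041), p53 targets (-0.0058), postsynaptic genes (-0.031), CA1 (-0.018) and cortex markers (-0.0014), while dentate markers changed from 0.0073 to -0.11 and passed (adjusted p = 0.00841, camera, limma). In the class from 8 to 16 they were p300 partners (-0.080), p53 targets (-0.018), postsynaptic genes (-0.038), dentate (-0.11), CA1 (-0.048) and cortex markers (-0.041), and in the classes from 4 to 16 p53 targets (-0.019) and dentate markers (-0.018). Without the 2 arrays they were deacetylases (-0.018), histone genes (-0.0045), p53 targets (-0.0052), heat shock genes (-0.0016), vesicle genes (-0.021), oxidative phosphorylation (-0.0084), oligodendrocyte (-0.0046) and cortex markers (-0.078).

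With each array left out in turn the choroid plexus list ran from 0.025 (without wild-type 2) to 1.14, interferon genes from 0.062 (without wild-type 1) to 0.12 and vascular markers from 0.064 (without wild-type 2) to 0.16. Lists that otherwise did not pass, but did with some array left out, were postsynaptic genes (-0.097 to 0.14), vesicle genes (-0.13 to 0.15), ribosomal genes (-0.11 to 0.038), heat shock genes (-0.041 to 0.086), activity-regulated genes (0.00021 to 0.098) and interneuron markers (0.026 to 0.13). Erythroid markers, which also passed in the other settings above, ran from 0.059 to 0.28. All these calls used the preset correlation of 0.01. The estimated correlations over all 6 arrays were 0.67 (ribosomal), 0.29 (vesicle), 0.29 (heat shock), 0.24 (erythroid), 0.15 (postsynaptic), 0.043 (interneuron) and 0.042 (activity-regulated). Lists that changed sign without passing were deacetylases (-0.024 to 0.046), acetyltransferases (-0.12 to 0.031), p300 partners (-0.059 to 0.083), p53 targets (-0.0057 to 0.012), histone genes (-0.0095 to 0.033), oxidative phosphorylation (-0.063 to 0.057), precursor (-0.065 to 0.012), dentate (-0.042 to 0.074), CA1 (-0.089 to 0.11), CA3 and CA2 (-0.021 to 0.037), thalamus (-0.0095 to 0.048), cortex (-0.038 to 0.074), microglia (-0.069 to 0.11) and oligodendrocyte markers (-0.0100 to 0.086). The Crebbp probe set 1434633_at ran from -0.13 to 0.056 and 1436983_at from -0.86 to -0.27.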

Other observations

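Transcripts of some pituitary hormones, chosen after their values were seen, differed between pools without following genotype. Growth hormone (Gh), read by 4 probe sets, lay at -3.22 to -2.60 in wild-type 3 and at -1.43 to -1.05 in p300+/- 1, as log2 relative to the median over the 6 arrays. The same probe sets lay at 1.23 to 1.42 in wild-type 2, at 0.66 to 0.79 in p300+/- 2, at 0.58 to 0.82 in p300+/- 3 and at -0.79 to -0.58 in wild-type 1. Prolactin (Prl) was at -3.04 in wild-type 3 and -1.46 in p300+/- 1, and between -0.51 and 0.70 in the other arrays. The alpha subunit shared by the glycoprotein hormones (Cga) was at 2.65 in wild-type 2 and between -0.68 and 0.55 elsewhere. Among the other hormone genes measured, Fshb was at 0.99 in wild-type 2, and its remaining values (-0.054 to 0.17) had the same signs as those of Gh in every array. Pomc, Tshb and Lhb did not. Pomc, read by 2 probe sets, was at -1.39 and -1.12 in wild-type 3 but at 0.77 and 0.19 in wild-type 1, and Tshb lay between -0.38 and 0.25. Lhb was higher in all 3 p300+/- arrays (0.018 to 0.23) than in the wild-type arrays (-0.24 to -0.018), a log2 fold change of 0.24 ± 0.12 (SE) that did not pass.

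The explanations in the following paragraphs, and the rules for judging them, were all chosen after the patterns had been seen. The estimated correlation and the omission of single arrays, on which some of them rest, were planned. The choroid plexus list was higher in p300+/- pools, and a genotype difference as its whole source is argued against by the mean log2 fold change of 0.069 ± 0.23 (SE) that was left without wild-type 2, in place of 0.73. The difference shared by p300+/- 3 and wild-type 2 is argued against too, since the list stood at 0.35 in p300+/- 3. A candidate explanation is that the wild-type 2 pool held less choroid plexus, which lies against the hippocampus and can come away with it: 22 of the 23 markers were lowest in that array, with the 4 Ttr probe sets at -3.20 to -2.06 and the list mean at -1.93 relative to the median over the 6 arrays. How many of these markers the hippocampus itself expresses cannot be read from centred values, and 1 of them (Igfbp2) is also in the vascular list.

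p300+/- 3 and wild-type 2 stood apart by at least 55.9 from the other arrays on the first principal component, and genotype is argued against by the difference of only 1.18 between genotype means on it. A lower share of neurons would raise the markers of all other cell types alike, but the shift of microglia markers exceeded that of oligodendrocyte markers by 0.36 ± 0.12 (SE over genes). That SE takes genes as independent, whereas the estimated correlation between the microglia genes was 0.39. Oligodendrocyte markers also differed between the 2 arrays, at 0.063 in p300+/- 3 and -0.12 in wild-type 2. The comparison therefore cannot decide against a lower share of neurons. Neuronal lists did not all fall in these arrays. Vesicle (-0.36 ± 0.076, SE over genes), postsynaptic (-0.30 ± 0.063) and CA1 lists (-0.24 ± 0.11) were lower. Interneuron (0.068 ± 0.099), CA3 and CA2 (0.11 ± 0.090), precursor (-0.0086 ± 0.092) and dentate lists (-0.083 ± 0.11) were not clearly so. These SEs take genes as independent as well. The first 2 bright probe sets of a gene shifted together across 2427 genes (r = 0.56, Spearman 0.61, genes not being independent replicates). The 8 other pairs of a p300+/- and a wild-type array gave r of 0.32 to 0.55, so the 0.56 was little above them. However, 103 genes had probe sets over 1 log2 unit apart, against at most 22 for those 8 pairs. That count decides nothing about how the transcripts were read, because the pair was singled out for its large contrast (SD of the shifts 0.37, against at most 0.25). Shortening of the labelled RNA stays open, since the 5' minus 3' shift of 4 control genes was 0.048 ± 0.033 (SE) and only 2 of them had a bright 5' probe set.

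Interferon-stimulated genes were higher in p300+/- pools at the preset correlation. Shared scatter of these genes between arrays may account for the call, which was lost with an estimated correlation (adjusted p = 0.752, camera, limma). A higher share of microglia cannot be told apart from it, because the microglia list had a mean log2 fold change of 0.050 ± 0.15 (SE over arrays), an interval that holds the 0.12 of the interferon list. Genotype stays open as well, with the means of the 3 p300+/- arrays above those of the 3 wild-type arrays and an exact two-sided permutation p of 0.1, the smallest that 3 against 3 arrays can give. The hypoxia list, which did not pass, separated in the same way. Its array means were 0.0017 to 0.10 in p300+/- and -0.085 to -0.037 in wild-type pools.

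The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. Any split has at least 0 probe sets past the threshold, so the 10 of 10 was fixed in advance and says nothing; the highest other count was 577 (limma). At least 550 probe sets at an unadjusted p under 0.05 were found in 8, the highest other count being 7237, and at least 3 called gene lists in 7, the highest other count being 10. The split of p300+/- 1, wild-type 1 and wild-type 3 against p300+/- 2, p300+/- 3 and wild-type 2 gave the 577, a structure of the samples that does not follow genotype.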
